A study of Mus musculus with 6 samples.

How the data were processed

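Tumours of AT3 breast cancer cells were grown in 3 WT and 3 Slc7a5.TKO mice, and CD45+ cells were isolated from them after collagenase digestion. Libraries were made with 10x 3' V3 reagents. The submitters' processing notes name Cell Ranger 7.1.0 and the mouse genome build mm10. The settings of read alignment and of cell calling are not given in the sources used here. For each of the 6 libraries the authors deposited a list of barcodes called as cells and a list of 32285 genes. The 6 gene lists were identical, and no barcode occurred more than once within a list. For WT replicate 2 the matrix deposited by the authors holds raw UMI counts per gene and barcode, in whole numbers with no normalization. The matrices of the other 5 libraries were not analysed here.

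Numbers of barcodes were compared between WT and Slc7a5.TKO (n = 3 each) by a two-sided exact permutation test of the difference in means over the 10 distinct splits. Barcodes shared by each of the 15 pairs of libraries were counted against 1 common pool size fitted to all pairs.

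In WT replicate 2, 22905 genes were detected, and the median mitochondrial share was 2.64% of UMIs. Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 5675 of 5698, as 23 were above 10%. Scrublet in scanpy 1.11.5 marked 7 barcodes (0.123%) as doublets. By the rule for a marked share under 0.5%, the 5% with the highest scores were to be removed instead: 245 barcodes scored above that limit, barcodes tied at it were kept, and 5430 were left. Counts were scaled to 10000 per barcode and log-transformed. Clusters were made from 2000 variable genes, 30 principal components, an exact graph of 15 nearest neighbours with shared-neighbour (Jaccard) weights and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Genes of the 12 compared lists, mitochondrial, ribosomal protein and receptor variable genes were left out of the variable genes. T-like barcodes were clustered again with 1500 variable genes and 20 components. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene places and lengths came from GENCODE M21, in which 32235 of 32285 gene IDs (99.8%) were found.

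A cluster took a cell type's name when at least 3 markers of that type had 20 UMIs or more, were seen in at least 5% of its barcodes and were at least 1.5 times above the other barcodes. It stayed unnamed when its 10 leading genes held more markers of another type, or when it was over 3 times shallower than the library's median and had no marker among them. The rule as first written also named cluster 8 fibroblast (Col3a1, Dcn and Pdgfra), T sub-cluster 2 naive or memory CD8 (Satb1, Cd8a and Cd8b1) and T sub-cluster 4 activated CD8 (Pdcd1, Lag3, Entpd1, Cd8a and Cd8b1). After these names were seen, the rule was tightened. It now needs a mean log2 fold of at least 0.8 over the markers and compares a cluster's leading genes with every class. Within T sub-clusters it does not count Cd3e, Cd3d, Trac, Cd4, Cd8a and Cd8b1 among the 3 markers needed. Of the conventional CD4 markers only Cd40lg then counts, so that name could not be given. The tighter rule leaves cluster 8 unnamed and removes the comparison of activated with naive or memory CD8 cells that was planned. Its values under the first rule are given with the effects of the other alternatives. The grouping of clusters 5 and 8 as Krt18-high was also made after the data were seen. Myeloid-like barcodes are the macrophage-like, monocyte-like and neutrophil-like ones together. Classes of under 20 barcodes were not compared.

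UMIs were summed over the barcodes of a class and given as counts per 1000000 UMIs (CPM), with exact Poisson 95% intervals. Shares of barcodes have exact Clopper-Pearson 95% intervals, and folds of CPM have intervals from the binomial distribution of 1 count given the sum of both. A count of 0 is given with the level that 3 counts would make. List members with at least 30 UMIs over both sides were measured. Each list was summarised by its median log2 fold (with 0.5 added to each count), by an interval from 1000 Poisson resamplings, and by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A single library gives no test between animals, so there are no p-values for genes. Of the 14 lists, 12 were compared, and the CTL effector list and the list of inhibitory receptors and Tox give levels only. Mars1 and Mx1 are not in the gene list under these symbols. The named genes are Slc7a5 and Slc3a2 in every comparison and, of each list, up to 4 measured members with the largest fold of at least 1.5 either way. Of the classes, the 3 with the highest level and the 1 with the lowest are named. Levels of Krt18, Ptprc, Hbb-bs, Lyz2, Apoe, Adgre1, Treml4, Gzmf, Cpa3, S100a8 and Ncr1, and counts of Ido1 and Cyp1a1, were chosen after their values were seen, as signs of RNA from other cells or of genes under the limit. So were the median folds of the macrophage, monocyte and neutrophil markers with at least 30 UMIs over both sides, together and by class, and the number of barcodes named NK among cycling and other T-like ones. The lists, markers, comparisons, filters, the rule for named genes and the first set of alternatives were fixed before the data were examined.

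On simulated data, 200 of 12319 genes were changed between T-like and myeloid-like barcodes. The fold intervals held the true fold for 94.0% of genes changed 1.5 times, 92.4% of those changed 2 times and 95.5% of those changed 4 times. Of 40 lists with no change, 2 lay outside the middle 95% of random lists. The simulated counts were drawn from the Poisson distribution that the intervals assume, so this checks the calculation only. Real counts vary more: in the T-like cluster the median variance between barcodes was 2.17 times the Poisson variance. This covers genes of at least 100 CPM, so not scarcer ones such as Slc7a5. Real intervals may therefore be too narrow.

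The alternatives tried were leaving out each library in turn, a replicate block, a log2 scale and medians for the barcode numbers. For WT replicate 2 they were no filter on barcodes, at least 500 genes with at most 5% mitochondrial UMIs, doublets kept, resolution 0.5 or 2, and list genes not left out of clustering. Further ones were clusters from one part of the UMIs with levels from the rest, barcodes thinned to 1 depth with shallower ones left out, a mean over barcodes, and totals without mitochondrial and ribosomal protein genes. Those added after seeing the data began with the T-like barcodes with the fewest UMIs of other cell types (76 of 151). Others left out the Krt18-led T-like sub-cluster or the T-like barcodes named NK at resolution 2, or used the naming rule as first written. Krt18-led means that Krt18 is among the 10 leading genes, where Mmp3, Il33, Dcn and Lum come before it.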

Results

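CD45+ cells (CD45 is the surface protein of white blood cells) were profiled by droplet single-cell RNA sequencing from AT3 breast tumours grown in 6 mice. The WT mice (n = 3) carried floxed Slc7a5, and the Slc7a5.TKO mice (n = 3) lacked Slc7a5 in T cells only. Slc7a5 is the light chain of a transporter for large neutral amino acids such as tryptophan and leucine, and Slc3a2 is its partner chain. The series asks how the expansion and effector functions of cytotoxic T cells in the tumour depend on tryptophan uptake through Slc7a5. Lists of the barcodes called as cells were used for all 6 libraries, and a matrix of UMI counts (a UMI marks 1 captured RNA molecule) for 1 library, WT replicate 2. The matrices of the other 5 libraries were not analysed here, so gene expression was not compared between genotypes, and Slc7a5 in the Slc7a5.TKO libraries was not analysed here. The matrix of WT replicate 2 held 134087464 UMIs in 5698 barcodes, with a median of 15746 UMIs (range 502 to 252616) and 3482 genes per barcode. The total UMI counts of the other 5 libraries are unknown.

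The first comparison asks whether the number of barcodes called as cells differed between genotypes. Slc7a5.TKO tumours gave 21059, 27805 and 26886 barcodes called as cells, and WT tumours gave 27857, 5698 and 18316. The mean was 25250 ± 3658 (SD, n = 3) in Slc7a5.TKO and 17290 ± 11115 (SD, n = 3) in WT, a ratio of 1.46. The difference of 7960 barcodes was smaller than the spread between WT libraries. A two-sided exact permutation test gave p = 0.4, where the smallest p that 3 against 3 libraries allow is 0.1. The ratio was 1.09 without WT replicate 2 and 2.10 without WT replicate 1, so it rested on single WT libraries. The number of barcodes also depends on how many cells were loaded, which is not given in the sources used here, and it is not a count of T cells. Nor is it a count of CD45+ cells. In WT replicate 2, 46.6% of kept barcodes lay in clusters 1 and 2, which hold RNA of many cell types. A further 9.48% lay in Krt18-high clusters with little RNA of the CD45 gene.

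**Figure D1:**
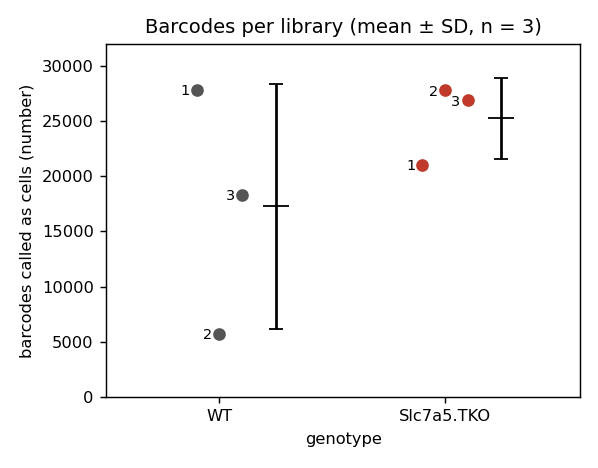
Number of barcodes called as cells (vertical axis) in each WT and Slc7a5.TKO library (points, numbered by replicate), with the mean and SD of 3 libraries beside them. WT replicate 2, at 5698, lies below the other 5 libraries.

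Barcode lists can also show whether a pair of libraries holds the same droplets. The 6 lists held 127621 barcodes, of which 125901 were distinct. Each of the 15 pairs of libraries shared 23 to 208 barcodes. With 1 common pool of 3805103 barcodes for all pairs, the shared number was 0.839 to 1.14 times what the pool predicts. The pool implied by Slc7a5.TKO replicates 2 and 3 (165 shared, 196 predicted) had an interval of 3889805 to 5310019, above the common pool, and the intervals of the other pairs held it.

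In WT replicate 2, macrophage-like cells were the largest named class, here and in all 7 alternatives, and T-like cells were a small share. Macrophage-like barcodes (C1qa, Apoe and other tissue macrophage genes) made up 16.6% of the 5430 barcodes kept (exact Clopper-Pearson 95% interval 15.6 to 17.6%, n = 902). Neutrophil-like barcodes made up 7.33% (6.65 to 8.06%, n = 398) and monocyte-like barcodes 7.03% (6.37 to 7.75%, n = 382). T-like barcodes made up 2.78% (2.36 to 3.25%, n = 151), erythroid-like 3.04% (n = 165), mast-like 2.89% (n = 157) and fibroblast-like 2.5% (n = 136). The shares and order of these classes moved with the settings far beyond the intervals, in part because other clusters took their names. With at least 500 genes and at most 5% mitochondrial UMIs, neutrophil-like was 14.5%, erythroid-like 11.8%, mast-like 8.64%, monocyte-like 7.84%, fibroblast-like 5.04% and T-like 4.30%. The mast-like cluster of that setting was led by mitochondrial genes. Monocyte-like was 2.89% without a filter. Fibroblast-like was 8.63% with doublets kept, where the cluster of that name had Rhox2d and Lsm7 of cluster 5 among its leading genes. Erythroid-like was 6.46% at resolution 2, where 187 of the barcodes of that name lay in a cluster led by Mgl2 and MHC class II genes. At resolution 0.5 no cluster took the monocyte, mast or fibroblast name. The mast-like name is doubtful: this cluster had 11.6 UMIs per 1000000 UMIs (CPM) of the mast cell protease gene Cpa3, and macrophage-like cluster 3 had 15.5 CPM. No cluster took the name of B, plasma, NK, dendritic, basophil, eosinophil, ILC2, endothelial or pericyte cells at the resolution used. None took the joint name of epithelial or tumour cells either. Intervals here and in what follows cover counting error only. With 1 library, no test was made on any of its values and no value says how mice differ.

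A further 57.8% of the kept barcodes (n = 3139) lay in 5 clusters that took no cell type name. Cluster 1 (30.5%, n = 1658) was led by mitochondrial genes, with a median mitochondrial share of 6.10% of UMIs. Cluster 2 (16.1%, n = 873) had a median of only 1647 UMIs per barcode. Clusters 5 (5.41%, n = 294) and 8 (4.07%, n = 221) had the most Krt18, a keratin gene of epithelial cells, at 174 and 122 CPM against 6.65 CPM in myeloid-like barcodes. Their Ptprc, the gene of CD45, was 44.6 and 65.5 CPM, and that of T-like barcodes was 210 CPM. Cluster 14 (1.71%, n = 93) was led by Mgl2 and MHC class II genes. RNA of one cell type was found in the barcodes of others: Hbb-bs, a haemoglobin gene of red blood cells, was at 5996 to 52657 CPM in all clusters but the erythroid-like one, and Lyz2, a myeloid gene, was at 14156 CPM in T-like barcodes.

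**Figure D2:**
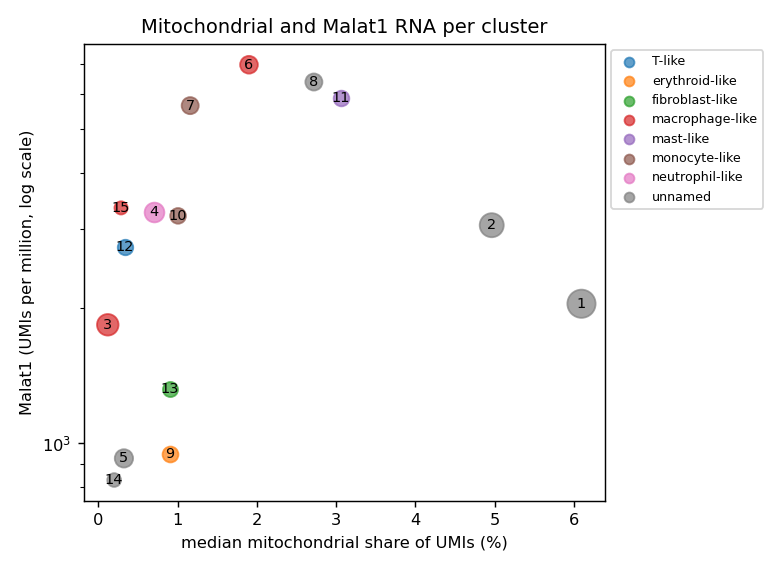
Median mitochondrial share of UMIs in percent (horizontal axis) and Malat1 in UMIs per 1000000 (vertical axis, log scale) for the 15 clusters of WT replicate 2 (circles, numbered, larger with more barcodes). Clusters 1 and 2 have the highest mitochondrial shares, and macrophage-like cluster 6 the highest Malat1, a nuclear RNA.

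Slc7a5 was highest in the Krt18-high clusters and low in most barcodes named as immune cells in this WT tumour. It was at 33.1 CPM in cluster 8 (exact Poisson 95% interval 30.2 to 36.3) and 21.5 CPM in cluster 5 (19.4 to 23.9), or 26.9 CPM (25.1 to 28.8) in both together. The next highest level was 14.3 CPM (11.7 to 17.3) in the mast-like cluster, whose Krt18 was 66.3 CPM. T-like barcodes had 5.82 CPM (3.90 to 8.36) from 29 UMIs, macrophage-like barcodes 2.57 CPM (1.95 to 3.32), and cluster 14 the lowest level of the classes and unnamed clusters, 1.87 CPM. T-like barcodes also held Lyz2 at 14156 CPM, against 20822 CPM in myeloid-like ones. Their Slc7a5 level is thus that of mixed RNA, and the level in T cells themselves may be higher or lower. Cluster 1, led by mitochondrial genes, had 13.7 CPM (12.5 to 14.9), above the T-like level. Slc3a2 was far more abundant: it was at 128 CPM (118 to 138) in T-like, 158 CPM in monocyte-like and 34.3 CPM in erythroid-like barcodes. Slc7a5 (ENSMUSG00000040010) lies on chromosome 8, from 121881150 to 121907694 on the minus strand of GRCm38, and Slc3a2 (ENSMUSG00000010095) on chromosome 19, from 8706882 to 8723369 on the minus strand. The T-like level was 3.67 CPM without a filter on barcodes and 3.85 CPM with the stricter filter. It was 3.84 CPM without the T-like sub-cluster that has Krt18 among its leading genes. The level in the Krt18-high clusters was 21.5 CPM when cluster 8 was counted as fibroblast-like, and 41.6 CPM when mitochondrial and ribosomal protein genes were left out of the total.

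**Figure D3:**
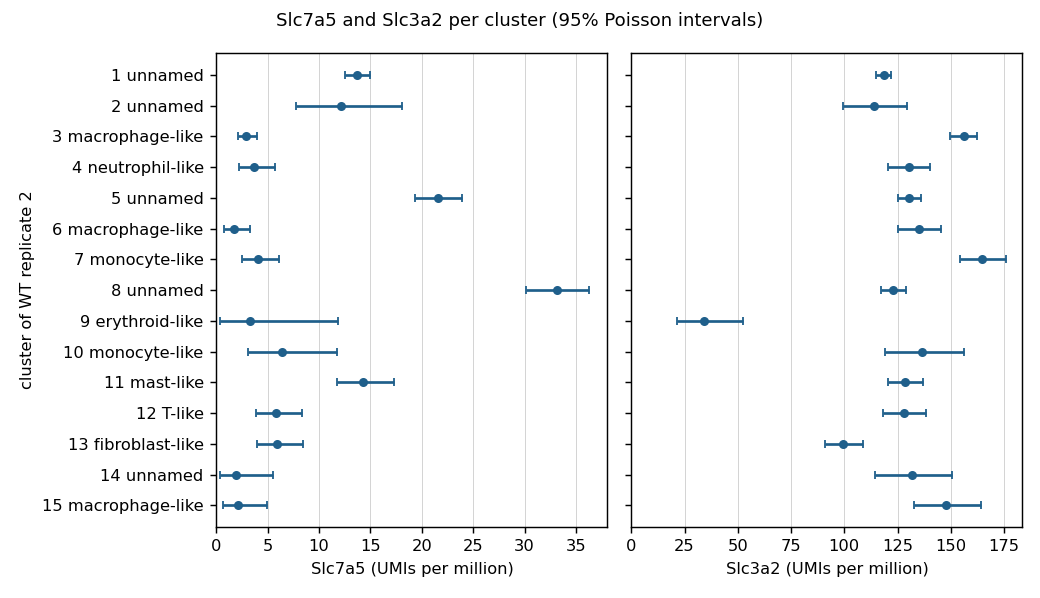
Slc7a5 (left) and Slc3a2 (right) in UMIs per 1000000 in each of the 15 clusters of WT replicate 2 (points), with 95% Poisson intervals (bars). Slc7a5 is highest in clusters 8 and 5, at 33.1 and 21.5, and the T-like cluster lies at 5.82.

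T-like (n = 151) and myeloid-like (n = 1682) barcodes were compared to ask which amino acid transport and amino acid response genes mark T cells in the tumour. Slc7a5 was 1.86 times higher in T-like barcodes (5.82 against 3.14 CPM, interval of the fold 1.19 to 2.81), while Slc3a2 was slightly lower (fold 0.859, 0.790 to 0.933). Genes of Myc and ribosome biogenesis, which serve growth, were higher in T-like barcodes as a group, and so were genes of the amino acid response driven by Atf4. Krt18 was higher too (fold 6.04), and with clusters made from one part of the UMIs and levels from the rest, the medians of these lists fell to 0.23 and 0.04. Large neutral amino acid transporters as a group, interferon response genes and genes by which myeloid cells suppress T cells were lower, by about as much as myeloid marker RNA found in T-like barcodes. Lyz2 was at 14156 CPM in T-like against 20822 CPM in myeloid-like barcodes (fold 0.680), Apoe at 8604 against 11756 CPM (fold 0.732), and 24 myeloid markers had a median log2 fold of −0.51. T-like levels of genes with folds near or below these are therefore not read as expression by T cells. Other T-like levels are those of mixed RNA too, and their folds may differ from those of T cells alone. The Slc7a5 fold turned to 0.992 when CPM was averaged over barcodes, and its interval reached below 1 in 8 of the 14 alternatives.

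Of the 8 measured members of the large neutral amino acid transport list, 2 were at least 1.5 times higher and 1 at least 1.5 times lower in T-like barcodes. The median log2 fold was −0.43 (interval −0.53 to −0.25), at the 0.12 percentile of random lists matched on expression. Besides Slc7a5, Slc7a6 was higher (7.43 against 4.14 CPM, fold 1.80, 1.22 to 2.59), and Slc16a10, a carrier of aromatic amino acids, was lower (15.7 against 26.5 CPM, fold 0.592, 0.463 to 0.746). Other amino acid transporters went both ways, with a median of 0.04 (−0.40 to 0.13, percentile 67.8, 11 members). In that list the glutamine carrier Slc1a5 was higher (28.1 against 16.3 CPM, fold 1.73, 1.43 to 2.08), and the cystine carrier Slc7a11 (fold 0.649) and the arginine carrier Slc7a2 (fold 0.659) were lower.

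Tryptophan catabolism genes were scarce, and 6 of 14 could be measured, with a median of 0.12 (−0.49 to 0.62, percentile 55.9). Kmo, the kynurenine hydroxylase, had 1 UMI in T-like and 53 in myeloid-like barcodes (fold 0.133, 0.0033 to 0.773). Afmid, which makes kynurenine from its formyl precursor, was higher in T-like barcodes (8.23 against 3.74 CPM, fold 2.20, 1.51 to 3.15). Ido1, which starts tryptophan breakdown, had 0 UMIs in T-like and in myeloid-like barcodes, which allows up to 0.602 and 0.0856 CPM, and 2 UMIs in all kept barcodes. Aryl hydrocarbon receptor genes, which kynurenine can switch on, had a median of −0.27 (−0.45 to −0.05, percentile 8.51), and none of 4 measured members reached 1.5 times. Their target Cyp1a1 had 0 UMIs in all kept barcodes, which allows up to 0.0242 CPM.

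In the Atf4 list, 5 of 14 measured members were at least 1.5 times higher in T-like barcodes and 0 lower, with a median of 0.52 (0.32 to 0.68, percentile 100). Phgdh, the first enzyme of serine synthesis, was at 53.6 against 13.4 CPM (fold 3.99, 3.42 to 4.65), and the asparagine synthetase Asns at 25.1 against 11.8 CPM (fold 2.13, 1.73 to 2.60). Aldh18a1, of proline synthesis, had a fold of 1.98 (1.53 to 2.54), and Chac1 a fold of 2.45 (0.947 to 5.67). In the Myc and ribosome biogenesis list, 10 of 16 members were at least 1.5 times higher and 0 lower, with a median of 0.66 (0.54 to 0.73, percentile 100). Myc was at 73.3 against 27.8 CPM (fold 2.63, 2.33 to 2.97), Npm1 at 995 against 554 CPM (fold 1.80, 1.74 to 1.85), Rrs1 had a fold of 1.86 and Nop58 of 1.80. The Krt18-high clusters 5 and 8 held more of these RNAs still, with 286 and 204 CPM of Phgdh and 242 and 270 CPM of Myc, and Krt18 was 40.2 CPM in T-like barcodes. Of the T-like barcodes, 26 formed a sub-cluster with Krt18 among its leading genes, after Mmp3, Il33 and the fibroblast markers Dcn and Lum. Leaving it out may therefore remove RNA other than that of the Krt18-high clusters. Without these 26 barcodes, the medians were 0.36 for Myc, 0.16 for Atf4 and −0.24 for large neutral amino acid transport genes. With clusters from one part of the UMIs, the last of these was −0.24 as well.

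Aminoacyl-tRNA synthetase genes had a median of 0.18 (0.08 to 0.24, percentile 99.2), and none of 19 members reached 1.5 times. Glycolysis genes had a median of −0.12 (−0.16 to −0.06, percentile 22.4), with only the lactate carrier Slc16a1 past 1.5 times (12.2 against 7.05 CPM, fold 1.74, 1.29 to 2.31). Genes of the mTORC1 complex and its amino acid sensing had a median of −0.07 (−0.24 to −0.03, percentile 24.6). Without mitochondrial and ribosomal protein genes in the total, every log2 fold was higher by 0.13, and the medians of glycolysis and mTORC1 genes turned to 0.01 and 0.06.

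Interferon response genes had a median of −0.48 (−0.60 to −0.35, percentile 0.00), and 5 of 13 members were at least 1.5 times lower in T-like barcodes. The myeloid-like side includes monocyte-like cluster 7 (n = 222), whose leading genes include Cxcl10, Rsad2, Ifit1 and Isg15. Folds without this cluster were not computed, so the difference may not hold for the other myeloid-like barcodes. Rsad2 was at 58.0 against 121 CPM (fold 0.479, 0.424 to 0.540), Isg15 at 117 against 182 CPM (fold 0.643), Ifit1 had a fold of 0.519 and Irf7 of 0.618. Myeloid suppression genes had a median of −0.58 (−0.66 to −0.42, percentile 0.00), with 4 of 11 lower and 1 higher, against a median of −0.51 for the 24 myeloid markers. Nos2, which makes nitric oxide, was at 9.84 against 27.8 CPM (fold 0.353, 0.260 to 0.471), and Cd274, the gene of PD-L1, at 48.4 against 82.9 CPM (fold 0.584). Il10 had a fold of 0.210 from 2 UMIs in T-like barcodes (0.0249 to 0.789). Pdcd1lg2, the gene of PD-L2, was the higher one (10.8 against 5.71 CPM, fold 1.90, 1.38 to 2.58). Genes that tissue dissociation switches on had a median of −0.48 (−0.59 to −0.30, percentile 0.01), with Hspa1a (fold 0.422), Hspa1b (fold 0.488) and Atf3 (fold 0.512) lower. In the deeper barcodes alone (113 T-like and 807 myeloid-like), each thinned to 17792 UMIs, the medians were −0.18 for interferon and −0.14 for dissociation genes; 38 T-like and 875 myeloid-like barcodes were too shallow and left out, so both the depth and the cells differ.

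**Figure D4:**
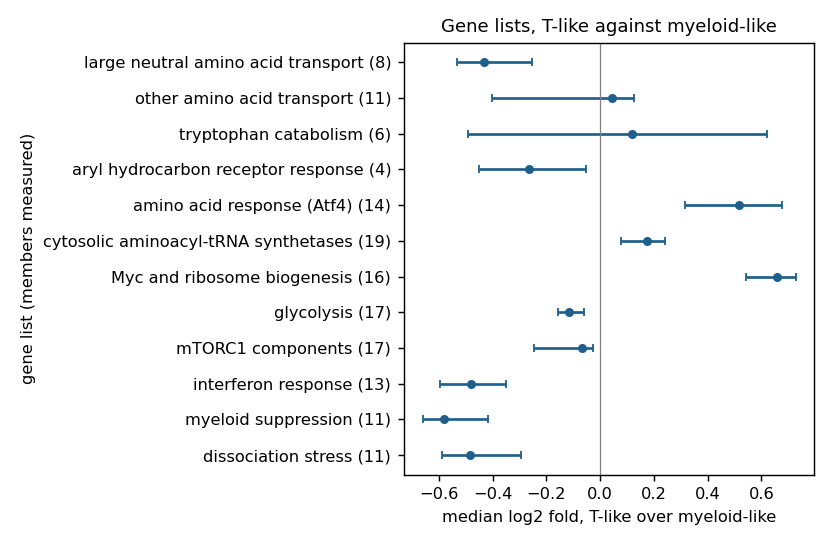
Median log2 fold of T-like over myeloid-like barcodes (horizontal axis) for 12 gene lists, with the number of measured members in brackets; bars are 95% intervals from resampled counts. Myc and ribosome biogenesis is highest, at 0.66, and myeloid suppression lowest, at −0.58.

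The T-like barcodes carried RNA of cytotoxic cells and almost no Cd4. Of 15 CTL effector genes, 12 had a T-like interval above the myeloid-like interval and 1 below it. Gzmc was at 949 CPM, Gzmf at 591 CPM, Ccl5 at 472 CPM, Nkg7 at 344 CPM, Gzmb at 144 CPM and Prf1 at 71.1 CPM. At resolution 2, 40 of these 151 barcodes took the name NK and held nearly all of the Gzmc and Gzmf RNA: the other 111 had 26.7 CPM of Gzmc, 4.49 CPM of Gzmf, 93.7 CPM of Gzmb, 41.3 CPM of Prf1 and 610 CPM of Ccl5. Of 10 genes of inhibitory receptors and Tox, which marks persistent stimulation, 8 lay above the myeloid-like interval and 1 below. Tox was at 69.1 CPM, Pdcd1 at 33.7 CPM, Ctla4 at 27.9 CPM and Lag3 at 21.5 CPM, while Havcr2 (46.4 against 39.6 CPM) and Entpd1 (84.3 against 104 CPM) were also abundant in myeloid-like barcodes. Cd8a was at 65.3 CPM, Cd4 at 1.41 CPM from 7 UMIs, and Foxp3, of regulatory T cells, at 3.21 CPM. The same UMIs formed the clusters, so these levels describe the T-like cluster and test nothing. The NK cell receptor gene Ncr1 was at 21.5 CPM.

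The T-like barcodes split into 5 sub-clusters of 35, 32, 31, 27 and 26 barcodes. Sub-cluster 2 was the cycling one, with Mki67 at 139 CPM. Slc7a5 was at 7.0 CPM (3.02 to 13.8) there and at 11.2 CPM (6.28 to 18.5) in sub-cluster 5, whose Krt18 was 126 CPM. Sub-cluster 1, rich in granzyme RNA, had 0 Slc7a5 UMIs, which allows up to 3.89 CPM. It also had the most Ncr1 of the 5, at 41.5 CPM. Sub-clusters 3, 4 and 5 held Gzmc as well (718, 1182 and 873 CPM against 2285 CPM), with Slc7a5 at 3.89, 2.85 and 11.2 CPM. The 0 UMIs are therefore not read as a trait of granzyme-rich T cells. No sub-cluster took the name of activated CD8, naive or memory CD8 or regulatory T cells under the tightened rule. That rule could not give the conventional CD4 name, as Cd40lg is the only marker of that class it counts. The rule as first written gave no sub-cluster the conventional CD4 or regulatory name. Activated were therefore not compared with naive or memory CD8 cells, nor regulatory with conventional CD4 cells.

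Cycling T-like barcodes (n = 32) were compared with the other T-like barcodes (n = 119) to ask which of the same genes differ in the cycling ones. Slc7a5 did not differ detectably at this depth (8 against 21 UMIs, fold 1.28, 0.490 to 3.01), nor did Slc3a2 (fold 1.02, 0.847 to 1.23). Large neutral amino acid transporters had a median of 0.50 (0.11 to 0.69), with 1 of 7 members at least 1.5 times higher in cycling barcodes. This lay at percentile 95.3, within the middle 95% of random lists, and the median over all 9037 genes measured was 0.15. The member was Slc7a7 (42.9 against 27.1 CPM, fold 1.58, 1.10 to 2.24). Macrophage RNA rose by about as much: all 8 macrophage markers were higher in cycling barcodes, with a median of 0.44 and folds of 1.21 (Apoe) to 1.6 (Adgre1), so the rises of this list and of Slc7a7 are not read as traits of cycling T cells. Aryl hydrocarbon receptor, Atf4, glycolysis and myeloid suppression genes were lower. RNA of some other cell types was lower as well: Krt18 was at 8.75 CPM in cycling against 49.5 CPM in other T-like barcodes, and the neutrophil gene S100a8 at 895 against 3665 CPM. The 7 neutrophil markers had a median of −1.80, the 7 monocyte markers one of −0.44 (folds of 0.557 to 8.20, the highest Treml4), and all 22 myeloid markers one of −0.42. The other T-like barcodes also held more NK-like cells: 35 of 119 took the name NK at resolution 2, against 5 of 32 cycling ones, and Gzmf had 1 UMI in cycling and 2944 in other barcodes. Without the barcodes named NK, the medians were 0.20 (−0.02 to 0.50) for large neutral amino acid transport, −1.05 for aryl hydrocarbon receptor, −0.35 for Atf4, −0.15 for glycolysis, −0.31 for interferon and −0.27 for myeloid suppression genes.

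Aryl hydrocarbon receptor genes had a median of −0.88 (−1.66 to −0.14, percentile 0.27), with 2 of 3 lower: Tiparp, a target of the receptor, at 21.0 against 55.8 CPM (fold 0.376, 0.236 to 0.575), and Ahr itself (fold 0.521, 0.227 to 1.06). Atf4 genes had a median of −0.34 (−0.62 to −0.16, percentile 0.02), with 4 of 12 lower: Asns (12.2 against 28.9 CPM, fold 0.423, 0.224 to 0.741), Ddit3 (fold 0.559), Shmt2 (fold 0.623) and Eif4ebp1 (232 against 367 CPM, fold 0.631). Glycolysis genes had a median of −0.23 (−0.31 to −0.15, percentile 0.04), with Slc2a3 (fold 0.381) and Hk1 (fold 0.520) lower among 17. Myc was at 33.2 against 85.2 CPM (fold 0.390, 0.271 to 0.547), while its list had a median of −0.04 (−0.19 to 0.14, percentile 5.09). Synthetase genes had a median of 0.29 (0.05 to 0.39, percentile 84.8), with Lars, the leucine synthetase, higher (fold 1.56, 1.11 to 2.17).

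Interferon genes went both ways, with a median of 0.14 (−0.14 to 0.32, percentile 34.9), 4 of 13 higher and 3 lower. Cxcl9 (175 against 76.9 CPM, fold 2.28, 1.89 to 2.73) and Gbp2 (fold 1.94) were higher, as macrophage markers were, so these rises are not placed in T cells, and Isg15 (fold 0.534) and Ifit2 (fold 0.479) lower. Myeloid suppression genes had a median of −0.60 (−0.84 to −0.19, percentile 0.02), with 5 of 10 lower, among them Ptgs2 (fold 0.184, 0.0488 to 0.491), Nos2 (fold 0.219) and Il1b (fold 0.508), beside the median of −1.80 for neutrophil markers. Dissociation genes had a median of −0.35 (−0.45 to 0.05, percentile 0.03). The mTORC1 genes had a median of 0.17 (−0.00 to 0.28, percentile 59.7), with Rragc higher (fold 1.59) and Deptor lower (fold 0.473). Other amino acid transporters had a median of 0.11 (−0.28 to 0.30, percentile 33.2), with Slc38a9, a lysosomal amino acid sensor, higher (fold 1.73) and Slc7a11 lower (fold 0.626). Only 1 tryptophan catabolism gene could be measured. Without the Krt18-led sub-cluster, the median was 0.20 for large neutral amino acid transport, −0.14 for Atf4 and 0.36 for Myc genes. In the T-like barcodes with the fewest UMIs of other cell types, myeloid suppression turned to 0.07 and dissociation to 0.15. Without a filter on barcodes, the interferon median was −0.54 and the Atf4 median −0.08. Over the 12 alternatives that gave a value, the Atf4 median ranged from −0.49 to −0.06.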

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

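The first naming rule and the T-like barcodes with the fewest UMIs of other cell types, without the Krt18-led sub-cluster or without those named NK at resolution 2 were chosen after the results were seen. The barcode ratio of Slc7a5.TKO to WT kept its direction in all 9 alternatives: 1.09 to 2.10 without 1 library each, 1.47 from medians and 1.76 on the log2 scale. A replicate block by label number gave 1.76 (exact sign-flip p = 0.5, a test that so few pairs keep from a small p), from ratios of 0.756, 4.88 and 1.47. Its estimate equals that of the log2 scale under any pairing, so these alternatives are not separate estimates. The labels do not say that the numbers pair the libraries.

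The T-like share was 4.30% with at least 500 genes and at most 5% mitochondrial UMIs, and 2.04% at resolution 2, where NK-like barcodes were split off. T-like Slc7a5 was 3.67 CPM without a filter, 3.85 with the stricter one and 3.84 without the Krt18-led sub-cluster. In the Krt18-high clusters it was 33.2 with doublets kept. There a cluster with Rhox2d and Lsm7 of cluster 5 among its leading genes took the fibroblast name and was not counted. The level was 22.6 at resolution 0.5, 23.4 with split UMIs, 22.3 in the barcodes deep enough to be thinned and 23.7 as a mean over barcodes. It was 41.6 without mitochondrial and ribosomal protein genes, and 21.5 under the first naming rule, which leaves out cluster 8. The T-like to myeloid-like fold of Slc7a5 was 1.10 with the stricter filter and 0.992 as a mean over barcodes, and 1.22 to 2.16 in the others. Large neutral amino acid transport had a T-like to myeloid-like median of −0.24 at resolution 2, −0.24 with split UMIs, −0.24 without the Krt18-led sub-cluster and −0.23 without the barcodes named NK. In cycling barcodes its median stayed above 0, at 0.20 to 0.56, in all 12 alternatives that gave a value; at resolution 2 and with split UMIs the cycling barcodes were under 20, so no value was had. A median counted as reversed when its interval lay wholly on 1 side of 0 and its sign changed. Medians with an interval that held 0 were not counted, though some changed sign, among them cycling interferon, dissociation and Myc genes. Reversed were the T-like to myeloid-like medians of glycolysis (0.00857) and mTORC1 genes (0.0592) without mitochondrial and ribosomal protein genes, where the total alone shifts every fold by 0.13. So was the cycling median of myeloid suppression (0.0666) in the T-like barcodes with the fewest UMIs of other cell types. Apart from that shift, the cause was not tested.

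Of the remaining values, 70 of 77 Slc7a5 levels, 15 of 38 class shares, 121 of 153 T-like to myeloid-like medians and 99 of 119 cycling medians stayed within their intervals. The first naming rule called sub-cluster 4 (n = 27) activated and sub-cluster 2 (n = 32) naive or memory CD8, but their leading genes are Gzmg with many of neutrophils (S100a9, Retnlg) in the one and of the cell cycle (Mki67, Top2a) in the other, so their comparison is not one of activated with naive cells. Its medians were −0.37 (−0.70 to 0.17, percentile 35.8) for large neutral amino acid transport, −0.26 for other amino acid transport, 0.34 for Atf4, −0.55 for synthetase, −0.84 for Myc, 0.24 for glycolysis, −0.31 for mTORC1, 0.56 for interferon, 0.35 for myeloid suppression and 1.01 for dissociation genes; the remaining lists had under 3 measured members. Depth limits the T-like values, with 29 Slc7a5 UMIs, and thinning left out 38 of the 151 T-like and 875 of the 1682 myeloid-like barcodes.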

Other observations

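All of the tests of explanations below but one, the count of genes for a cell type of its own, were chosen after the results were seen. At resolution 2, an alternative fixed in advance, the 151 T-like barcodes split into 111 T-like and 40 NK-like barcodes with different cytotoxic RNA. The NK-like barcodes held nearly all of the granzyme C, D, E and F RNA: Gzmc was at 3267 against 26.7 CPM, Gzmf at 2067 against 4.49 CPM, Gzmd at 1445 against 1.40 CPM and Gzme at 679 against 0.281 CPM. They also had more Gzmb (271 against 93.7 CPM), Prf1 (146 against 41.3 CPM) and the chemokine gene Xcl1 (174 against 36.5 CPM). The T-like barcodes had more Ccl5 (610 against 126 CPM), Gzmk (27.8 against 1.41 CPM), Ifng (25 against 2.82 CPM), Tox (90.4 against 15.5 CPM) and Pdcd1 (42.9 against 10.6 CPM). Slc7a5 was at 6.17 CPM (3.87 to 9.35) in T-like and 4.94 CPM (1.99 to 10.2) in NK-like barcodes, within each other's intervals, and Slc3a2 at 138 CPM (126 to 151) and 102 CPM (86.3 to 120), whose intervals do not overlap. The same UMIs formed these groups, so the levels describe them and test nothing, and none of the explanations that follow was tested against genotype, since only 1 WT library is used.

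Clusters 1 and 2, 46.6% of the kept barcodes, hold RNA of many cell types. For cluster 1, a cell type of its own is argued against by 0 genes of at least 50 CPM, outside the mitochondrial ones, that lay 1.5 times above every named class. Several whole cells per barcode in cluster 1 were tested by its summed T cell markers only, at 56.0 CPM against 623 CPM in T-like barcodes. Their variance was 1.195 times their mean at each depth, where whole T cells in some barcodes need far more. The clustering was free to use these markers, so it may have placed barcodes with a whole T cell elsewhere. Cells of other types were not tested, so several whole cells per barcode stay open. The median overdispersion over genes was 1.04 in cluster 1 and 1.07 in cluster 2, against 1.45 to 3.10 in the other clusters, so barcodes of cluster 1 may hold RNA from a shared pool without a whole cell. Cluster 2, with a median of 1647 UMIs, was not tested for the other explanations and stays open.

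Macrophage-like cluster 6 had more mitochondrial and long-gene RNA than macrophage-like cluster 3: the mitochondrial share was 1.94% against 0.394%, and Malat1 6956 against 1835 CPM. RNA added from the shared pool would raise markers of other cell types as well, but across 8 such markers, S100a8 and S100a9 the most abundant, the observed rise was −0.544 times the one needed, that is, they were lower. A state of macrophages alone is argued against by the pair of Krt18-high clusters 8 and 5, whose folds across genes correlated with those of clusters 6 and 3 (Spearman rho 0.768, 10805 genes, which are not independent replicates). A difference in nuclear and mitochondrial against cytosolic RNA content stays open: the correlation of the fold with gene length (rho 0.637, and 0.663 for 8 over 5) restates the pattern and does not test it.

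Slc7a5 was 1.86 times higher in T-like than in myeloid-like barcodes, and RNA of Krt18-high barcodes captured with T-like cells cannot be told apart from a higher level in the T cells themselves. From the Krt18 excess of T-like barcodes, a share of 23.4% of such RNA would predict 8.69 CPM of Slc7a5. That is above the observed 5.82 CPM and its interval (3.90 to 8.36). The prediction assumes 1 ratio of Krt18 to Slc7a5, and the myeloid-like level of 3.14 CPM for the rest of the RNA. The overshoot does not show which assumption fails. The counting error of the prediction was not computed, and a smaller share stays open. Without the Krt18-led sub-cluster the fold was 1.22, with an interval of 0.648 to 2.14 that holds both no difference and the full fold. That sub-cluster had the fibroblast markers Dcn and Lum before Krt18 among its leading genes, so leaving it out may remove other RNA as well. In the 76 T-like barcodes with the fewest UMIs of other cell types it was 2.16. The few Slc7a5 UMIs keep both explanations open.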
